A study of Homo sapiens with 12 samples.

How the data were processed

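RNA was measured in HCA2 (MJ90) cells, an established line of human skin fibroblasts, carrying a doxycycline-inducible short hairpin against luciferase (shLuc, the control) or against FBXO22 (shFbxo22). Each hairpin was studied in young cells at low passage and in cells made senescent with 10 Gy of ionizing radiation, which gives 4 groups of 3 libraries, 12 libraries in all. Per the labels' protocols, cells were grown in DMEM with 10% fetal bovine serum, total RNA was purified on RNeasy columns, and libraries were made with an Ion Total RNA-Seq kit. Groups and replicate numbers came from the sample titles. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

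The data used here were 4 tables of the authors' own comparisons, each setting 2 groups of 3 libraries against each other. Per the submitters' processing notes, the authors used Bowtie2 2.0.0, STAR 2.3.0, DESeq2 1.14.1 and R 3.2.2 with the builds hg19 and GRCh37, and the notes used here give these names without their roles. Each of the 55765 rows per table holds, per the file headers, a base mean (the authors' mean normalized count over the 6 libraries, a signal that is never negative). The authors deposited beside it a log2 fold change and its standard error. A Wald score was deposited as the test statistic, per the file headers. The p-value and its adjusted p-value were also deposited by the authors. Values per library were not analysed here, because the tables hold none. The design written before the data were examined foresaw this case, and the authors' deposited fold changes and adjusted p were then the main results, with a threshold of 0.05. Its other options, tests on counts or normalized values per library, were therefore not used.

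The authors' fold changes were moderated towards 0: their largest standard error was 0.697 in the table of senescent against young shLuc libraries and 0.333 in that of shFbxo22 libraries. A fold change of a gene with few reads is therefore understated, and by different amounts in different tables. A row without an adjusted p in the authors' table stayed without one and entered no count. This left 21889 genes tested for senescence in shLuc, 18758 for senescence in shFbxo22, 20082 for the hairpins in young cells and 22788 for the hairpins in senescent cells. Dates stood in place of gene symbols in 28 rows of every table, and these rows were left out. Gene symbols are printed as the tables give them (IL8 for CXCL8, CYR61 for CCN1, CTGF for CCN2, SEPP1 for SELENOP). No coordinates are given, since the tables hold none.

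The sign of each table's fold changes was settled from the numbers. A base mean and a fold change together give the mean of each group, and every group appears in 2 tables. Of the 16 possible choices of sign, 1 made the 2 estimates of each group's mean meet, with a mean absolute log2 difference of 0.0092 over the 9109 genes with a base mean of at least 200 in all 4 tables, against 0.1306 for the next choice. In that choice the shLuc senescence table and the young hairpin table keep their deposited sign, and the other 2 tables are turned. Fold changes credited below to those 2 tables therefore have the opposite sign in the deposit. All values below are senescent over young, or shFbxo22 over shLuc. Simulated tables with known signs were resolved for 16 of 16 choices over 8654 genes. They were built from the resolved group means, with small errors in the base means and none in the fold changes. Their recovery was therefore nearly fixed in advance and adds little to the choice of signs. Group means printed below are these reconstructed means, averaged over the 2 tables, and carry no error of their own. They are not reliable for genes whose fold change was strongly moderated, where the 2 tables can give different means, and are printed for single genes only where the 2 nearly meet.

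Whether the senescence response differed between the hairpins was tested per gene as the shFbxo22 log2 fold change minus the shLuc log2 fold change, over the root of the summed squares of the authors' 2 standard errors, as a normal z with Benjamini-Hochberg adjustment over 18598 genes. The design had foreseen limma standard errors and a t statistic here, and the authors' standard errors took their place because the tables hold no values per library. The 2 tables share no library. On simulated data for that comparison over 18598 genes, with 200 genes given a difference, the test found 57% of the log2 differences of 1 and 81% of those of 2, and 3.50% of its calls were unchanged genes. The simulation did not include the moderation of fold changes. Its unchanged genes were drawn from the normal errors that the test assumes, so the 3.50% does not check that assumption.

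In all, 22 gene lists were fixed before the data were examined: p53 targets, senescence-associated secretory factors, mitosis, DNA replication, homologous recombination, interferon-stimulated genes, matrix, contractile genes, cholesterol synthesis, lysosome, ATF4 targets, glutamine metabolism, glycolysis, NRF2 and BACH1 targets, NF-kB targets, histones, FBXO22 ligase subunits and substrates, and markers of keratinocytes, melanocytes, endothelium, blood cells and fibroblasts. Each was tested against all other genes with cameraPR of limma 3.58.1 in R 4.3.3 on the deposited Wald statistic, with a preset correlation of 0.01 and adjustment over 88 tests (lists times comparisons). An estimated correlation needs values per library, which the tables do not hold, so presets of 0.05 and 0.1 were run instead, and the value at 0.1 is given beside each call that it ends. Members of a list were counted as higher or lower by adjusted p over all genes tested; adjusted over the list alone, no count moved by more than 3 members. The list test on the difference of responses was added after the data were examined and was adjusted over 22 lists. On shuffled statistics of senescence in shLuc, over 21889 genes, 2.36% of lists passed p 0.05 in 100 draws, and a shifted list was found in 100 of 100. Shuffling removes the correlation between genes, so this rate does not cover lists whose members move together. The planted shift was large against the spread of all statistics, so weaker shifts were not tested.

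Genes were named by a rule fixed beforehand: FBXO22 and 11 further fixed genes, the 10 largest changes in each direction per comparison among called genes above the median base mean (5 for the difference of responses, with the base mean averaged over both senescence tables), and up to 4 members of each list with the smallest adjusted p. Symbols of clones, mitochondrial genes, short structural RNAs, ribosomal protein genes and sex-linked genes were left out of the largest changes. The rule's condition that 3 libraries of one group lie above the 3 of the other could not be applied without values per library. Some genes that the rule names are not reported here. Reads of histone genes can be shared between near-identical copies, and those of CDC20 with its pseudogene CDC20P1, so their single values are uncertain. Depth per library was not read from the tables. Genes seen as 1 read in 1 library put all size factors between 0.999 and 1.02. The implied total, a mean over the 6 libraries of each table, was between 22072900 and 22073996 counts before those factors. It may be a total set by scaling and not a sequencing depth. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.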

Results

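Transcript levels were compared between young and radiation-induced senescent HCA2 fibroblasts that carried a hairpin against luciferase or against FBXO22. FBXO22 is an F-box protein, the substrate-binding part of an SCF ubiquitin ligase. The 4 groups of 3 libraries form a design with senescence and hairpin as factors, and the authors' deposited tables give senescence within each hairpin and the hairpins within each state. The mean library total inferred from each of the 4 tables, over its 6 libraries, was between 22072900 and 22073996 counts before the authors' size factors. Totals so nearly equal may reflect scaling, so the depth of sequencing per library is unknown.

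The targeted gene was examined first. In young cells FBXO22 was lower with shFbxo22 than with shLuc, with a log2 fold change of -0.81 ± 0.15 (standard error; Wald test, adjusted p = 1.07e-06) in the authors' deposited table, a 1.75-fold reduction. In senescent cells it went against the label: FBXO22 was higher in the libraries labelled shFbxo22, by a log2 fold change of 1.01 ± 0.12 (Wald test, adjusted p = 7.91e-15) in the authors' deposited table after its sign was turned. The value as deposited has the opposite sign, so this direction rests on the sign settled from the base means. The reconstructed group means from the authors' deposited tables were 438 normalized counts in young and 371 in senescent shLuc libraries, and 254 in young and 746 in senescent libraries labelled shFbxo22. Directions drawn from the libraries labelled shFbxo22 senescent are therefore given for the label, not for a lower FBXO22 transcript level.

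**Figure D1:**
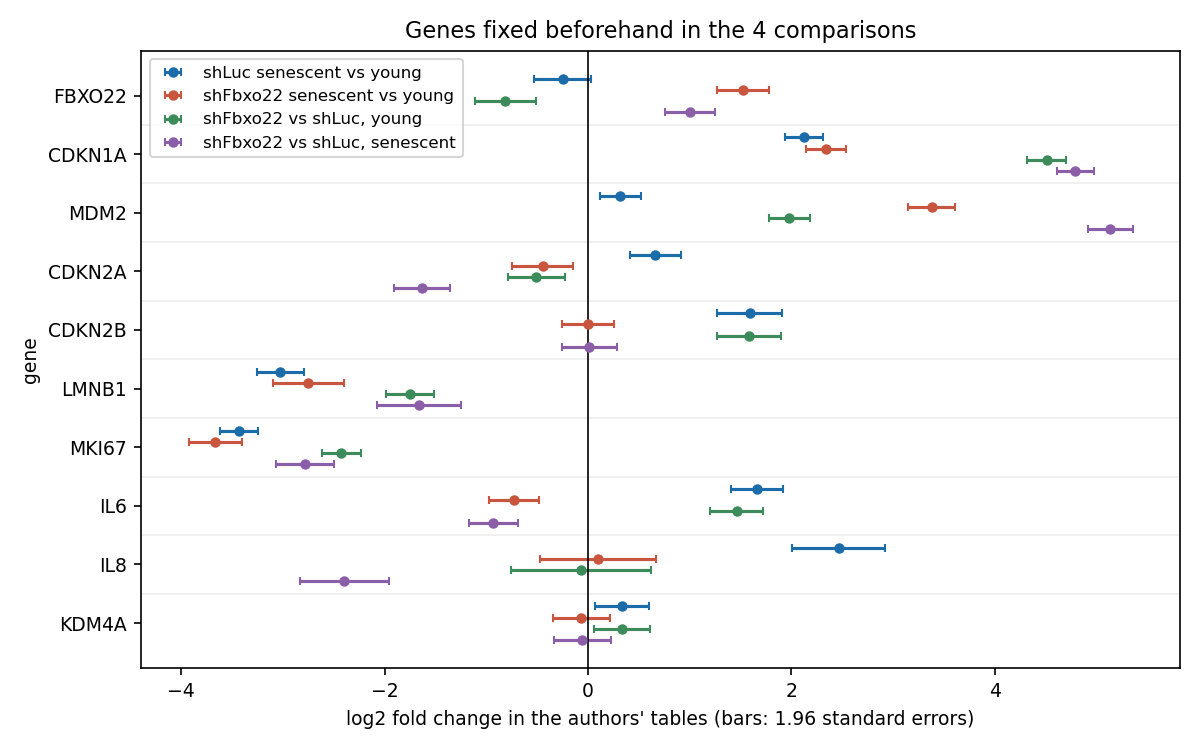
Log2 fold changes (horizontal axis) of 10 genes fixed beforehand (vertical axis) in the authors' 4 deposited tables, with bars for the 95% interval from the authors' standard errors. FBXO22 lies at -0.81 for the hairpins in young cells and at 1.01 in senescent cells, and CDKN1A lies above 2 in all 4 comparisons. Signs are those settled from the base means, with 2 of the 4 tables turned.

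With the control hairpin, senescent cells had lower transcripts of cell division, DNA replication, histones and the contractile apparatus and higher transcripts of interferon response, lysosome, cholesterol synthesis and secreted factors. MKI67, a proliferation marker, fell with a log2 fold change of -3.44 ± 0.10 and LMNB1, encoding the nuclear lamin B1, fell with -3.03 ± 0.12 in the authors' deposited table (adjusted p = 4.88e-276 and 7.37e-141). CDKN1A, encoding the cyclin-dependent kinase inhibitor p21, rose with 2.12 ± 0.10, CDKN2B with 1.59 ± 0.16 and CDKN2A with 0.66 ± 0.13 in the authors' deposited table. IL6 rose with 1.66 ± 0.13 and IL8 with 2.47 ± 0.23, both secreted inflammatory factors, in the authors' deposited table. MDM2, which encodes a ubiquitin ligase, rose by only 0.32 ± 0.10, and KDM4A, a histone demethylase, by 0.33 ± 0.14 in the authors' deposited table. FBXO22 itself was at -0.25 ± 0.14, which did not pass the test (adjusted p = 0.16) in the authors' deposited table. In total the authors' deposited table called 9321 of 21889 genes, 4651 higher and 4670 lower in senescent cells.

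All 44 tested members of the mitosis list fell in shLuc senescence, as did all 45 DNA replication genes and all 24 homologous recombination and Fanconi genes, at adjusted p over all genes in the authors' deposited table (camera adjusted p = 5.65e-202, 1.24e-60 and 7.2e-20). Of the mitosis genes, the cyclin CCNB1 was at a log2 fold change of -4.12 ± 0.10, CDC20 at -4.98 ± 0.11 and ANLN at -4.23 ± 0.09 in the authors' deposited table. RRM2 and TYMS, needed for making deoxynucleotides, were at -3.05 ± 0.11 and -2.80 ± 0.10 in the authors' deposited table. Of 55 histone genes 54 fell, with a median log2 fold change of -2.15 (camera adjusted p = 3.32e-53). Among contractile genes 24 of 25 fell, and 25 when adjusted over the list alone (camera adjusted p = 6.4e-27). These included TPM1 at -2.56 ± 0.08, CYR61 at -2.81 ± 0.11 and smooth muscle actin ACTA2 at -2.43 ± 0.11 in the authors' deposited table.

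Interferon-stimulated genes rose almost as a block in shLuc senescence, 36 of 37 with a median log2 fold change of 1.72 (camera adjusted p = 5.13e-53). MX2 was at 2.84 ± 0.09 and RSAD2 at 3.68 ± 0.15, both antiviral effectors, in the authors' deposited table. Lysosome genes rose in 40 of 48 cases (41 adjusted over the list alone; camera adjusted p = 1.06e-23), with the proteases CTSK at 3.58 ± 0.09 and CTSD at 1.77 ± 0.08 in the authors' deposited table. Of 25 cholesterol genes 21 rose and 1 fell (camera adjusted p = 3.44e-13), with HMGCS1 at 1.86 ± 0.09 in the authors' deposited table. Of 30 ATF4 and amino acid response genes 25 rose and 4 fell (camera adjusted p = 1.53e-15), with TRIB3 at 2.37 ± 0.09 in the authors' deposited table. Targets of NRF2 and BACH1 rose in 22 of 30 cases and fell in 3 (camera adjusted p = 5.13e-09), and the ferritin chain FTH1 was at 2.80 ± 0.09 in the authors' deposited table. Of 29 NF-kB targets 16 rose and 2 fell (camera adjusted p = 6.79e-06), with SOD2 at 2.99 ± 0.08 in the authors' deposited table. Of 45 secretory factors 31 rose and 10 fell (camera adjusted p = 1.19e-05). TNFAIP6 was at 2.69 ± 0.12 and STC1 at 1.94 ± 0.09, while MMP3 was at -2.06 ± 0.08, in the authors' deposited table.

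The p53 target list was mixed in shLuc senescence: 18 of 32 members rose, 6 fell and 8 did not pass (19 and 7 adjusted over the list alone). The list test gave camera adjusted p = 0.0178, and adjusted p = 0.244 with a preset correlation of 0.1. GDF15 was at 3.21 ± 0.18, TP53INP1 at 1.97 ± 0.15 and SESN2 at 1.46 ± 0.11 in the authors' deposited table. Fibroblast identity markers rose in 9 of 16 cases and fell in 3 (camera adjusted p = 0.000571, and adjusted p = 0.095 on ranks), with the proteoglycan DCN at 2.38 ± 0.09 in the authors' deposited table. Of 10 FBXO22 ligase subunits and substrates 5 rose and 2 fell (camera adjusted p = 0.0466, and adjusted p = 0.174 with a preset correlation of 0.1). KLF4 was at 2.11 ± 0.10 and BACH1 at 1.28 ± 0.09 in the authors' deposited table. Matrix genes split into 13 that rose and 13 that fell of 37 (camera adjusted p = 0.0685), with COL15A1 at 4.39 ± 0.16 in the authors' deposited table. Glutamine genes (5 up, 8 down of 19) and glycolysis genes (12 up, 12 down of 32) gave camera adjusted p = 0.168 and 0.781. Among genes above the median base mean, the largest increases in the authors' deposited table were ADH1B at 7.45 ± 0.39, GLDN at 5.43 ± 0.18, FER1L6 at 5.32 ± 0.33, AGT at 4.72 ± 0.18, CHI3L1 at 4.53 ± 0.12 and PTGDS at 4.45 ± 0.13. COL15A1, TMEM132B, MMP11 and PLXDC2 followed, between 4.39 and 4.25, in the authors' deposited table. Among the same genes, decreases were led, in the authors' deposited table, by CDC20, PLK1 at -4.65 ± 0.13, KIF20A at -4.50 ± 0.12, OXTR at -4.49 ± 0.11, SAPCD2 at -4.49 ± 0.21, the pseudogene CDC20P1 at -4.40, and F3, encoding tissue factor, at -4.34 ± 0.15.

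In the libraries labelled shFbxo22, senescent cells also had lower cell cycle transcripts, while 31 of 32 p53 targets rose and the interferon and cholesterol lists fell. MKI67 was at -3.67 ± 0.13 and LMNB1 at -2.75 ± 0.18, both lower (adjusted p = 1.05e-163 and 4.19e-51), in the authors' deposited table. CDKN1A rose with 2.34 ± 0.10 and MDM2 with 3.38 ± 0.12 in the authors' deposited table. IL6 fell with -0.73 ± 0.12 and CDKN2A with -0.44 ± 0.15 in the authors' deposited table. CDKN2B at 0.0010 ± 0.13, IL8 at 0.10 ± 0.29 and KDM4A at -0.065 ± 0.14 did not pass the test in the authors' deposited table. FBXO22 rose from young to senescent cells, with 1.53 ± 0.13 (Wald test, adjusted p = 1.06e-28), in the authors' deposited table after its sign was turned. The authors' deposited table called 3325 of 18758 genes, 1530 higher and 1795 lower.

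Of the 32 p53 targets 31 rose and 1 did not pass (median log2 fold change 1.38, camera adjusted p = 3.41e-109). TP53I3 was at 3.29 ± 0.09 and ACER2 at 3.11 ± 0.16 in the authors' deposited table. All 44 mitosis genes fell (camera adjusted p = 5.14e-239), 39 of 45 DNA replication genes fell and 2 rose (1.22e-44 by the same test), and 16 of 24 homologous recombination genes fell and 1 rose (1.59e-15). TOP2A was at -3.23 ± 0.13, RRM2 at -2.94 ± 0.14 and FANCI at -1.97 ± 0.14 in the authors' deposited table. Histone genes fell in 47 of 54 cases (camera adjusted p = 1.22e-106). Interferon-stimulated genes fell in 18 of 37 cases and rose in 1 (camera adjusted p = 2.16e-07), with MX1 at -0.95 ± 0.10 and OAS3 at -1.18 ± 0.10 in the authors' deposited table. Of 25 cholesterol genes 17 fell and none rose (camera adjusted p = 2.83e-12), with LSS at -1.09 ± 0.12 in the authors' deposited table. Glycolysis genes fell in 11 of 31 cases and rose in 3 (camera adjusted p = 0.0358, and adjusted p = 0.306 with a preset correlation of 0.1).

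The other lists did not pass in this comparison. Of 43 secretory factors 14 rose and 13 fell (camera adjusted p = 0.691), among them ICAM1 at -1.24 ± 0.10 in the authors' deposited table. Lysosome genes had 5 up and 4 down of 48, ATF4 genes 3 up and 6 down of 30, and NRF2 and BACH1 targets 4 up and 4 down of 30 (camera adjusted p = 0.919, 0.948 and 0.789). NF-kB targets had 1 up and 9 down of 28, contractile genes 5 up and 10 down of 25, and matrix genes 5 up and 11 down of 37 (camera adjusted p = 0.0611, 0.0685 and 0.528). Glutamine genes, FBXO22 partners and fibroblast markers gave camera adjusted p = 0.564, 0.77 and 0.0679. Among genes above the median base mean, the largest increases in the authors' deposited table were PDE4C at 5.91 ± 0.24, CLCA2 at 4.98 ± 0.13, INPP5D at 3.83 ± 0.18, then MDM2, TP53I3, ACER2, and ID1 at 3.04 ± 0.13 and ID3 at 2.97 ± 0.12. Among the same genes, decreases were led by HIST1H3G at -4.93 ± 0.20, HIST1H3B at -4.05 ± 0.15, CDC20 at -3.88 ± 0.16 and KIFC1 at -3.83 ± 0.20 in the authors' deposited table.

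Young cells already differed between the hairpins. CDKN1A was higher with shFbxo22 by a log2 fold change of 4.51 ± 0.10 in the authors' deposited table (adjusted p listed as 0), a 22.8-fold difference. MDM2 was higher with 1.98 ± 0.10, CDKN2B with 1.58 ± 0.16, IL6 with 1.46 ± 0.13 and KDM4A with 0.34 ± 0.14 in the authors' deposited table. MKI67 was lower with -2.43 ± 0.10, LMNB1 with -1.75 ± 0.12 and CDKN2A with -0.51 ± 0.14 in the authors' deposited table. IL8 at -0.065 ± 0.35 did not pass in the authors' deposited table. The authors' deposited table called 7218 of 20082 genes, 3753 higher and 3465 lower with shFbxo22.

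All 32 p53 targets were higher with shFbxo22 in young cells (median log2 fold change 1.52, camera adjusted p = 5.77e-56). SPATA18 was at 6.24 ± 0.27, EDA2R at 2.84 ± 0.13 and ZMAT3 at 2.40 ± 0.11 in the authors' deposited table. All 44 mitosis genes, 44 of 45 DNA replication genes, 21 of 24 homologous recombination genes and 54 of 55 histone genes were lower (camera adjusted p = 3.28e-148, 9.67e-59, 3.12e-24 and 4.65e-80). TOP2A was at -2.50 ± 0.10, RRM2 at -2.03 ± 0.10 and BRCA1 at -1.89 ± 0.12 in the authors' deposited table. Cholesterol genes were higher in 22 of 25 cases and lower in 1 (camera adjusted p = 2.31e-18), and lysosome genes higher in 35 of 48 and lower in 3 (3.28e-10 by the same test). HMGCS1 was at 2.22 ± 0.11 and CTSK at 1.75 ± 0.11 in the authors' deposited table. Secretory factors were higher in 21 of 43 cases and lower in 6 (camera adjusted p = 4.98e-08), with IGFBP5 at 3.99 ± 0.10 and IGFBP2 at 2.80 ± 0.19 in the authors' deposited table.

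Several weaker list calls in young cells ended with a preset correlation of 0.1. Interferon-stimulated genes had 16 higher and 7 lower of 37 (camera adjusted p = 0.00185, and adjusted p = 0.138 with that correlation). Their median log2 fold change was -0.01 while their mean was 0.28, and TRIM22 at 3.75 ± 0.12 and OASL at -2.20 ± 0.19 in the authors' deposited table lay at opposite ends. Matrix genes had 15 higher and 7 lower of 37 (camera adjusted p = 0.000967, and adjusted p = 0.114), ATF4 genes 15 and 4 of 30 (0.00651, and adjusted p = 0.174), and NF-kB targets 13 and 1 of 29 (0.00266, and adjusted p = 0.124). Glutamine genes had 3 higher and 7 lower of 19 (camera adjusted p = 0.0256, and adjusted p = 0.196), and fibroblast markers 7 and 3 of 15 (0.00525, and adjusted p = 0.0837). Contractile genes, NRF2 and BACH1 targets, glycolysis genes and FBXO22 partners gave camera adjusted p = 0.691, 0.58, 0.125 and 0.349. Among genes above the median base mean, HEPH at 5.15 ± 0.24, SEPP1 at 4.02 ± 0.18, SULF2 at 3.59 ± 0.14 and CYFIP2 at 3.56 ± 0.21 were among the largest increases in the authors' deposited table. NPTX2 at -6.71 ± 0.30, NEFH at -4.80 ± 0.20, ACTC1 at -4.04 ± 0.19 and STAG3 at -4.02 ± 0.18 led the decreases among them in the authors' deposited table.

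In senescent cells, the libraries labelled shFbxo22 had higher p53 targets and contractile genes and lower interferon, lysosome, ATF4 and NRF2 genes than the shLuc libraries, while FBXO22 itself was higher. MDM2 was higher with a log2 fold change of 5.14 ± 0.11 and CDKN1A with 4.80 ± 0.09 in the authors' deposited table (adjusted p listed as 0 for both). IL8 was lower with -2.40 ± 0.22, CDKN2A with -1.63 ± 0.14 and IL6 with -0.93 ± 0.12 in the authors' deposited table. MKI67 was lower with -2.78 ± 0.14 and LMNB1 with -1.66 ± 0.21 in the authors' deposited table. CDKN2B at 0.01 ± 0.14 and KDM4A at -0.05 ± 0.14 did not pass in the authors' deposited table. The authors' deposited table called 9140 of 22788 genes, 4608 higher and 4532 lower in the libraries labelled shFbxo22 senescent.

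All 32 p53 targets were higher in the libraries labelled shFbxo22 senescent (median log2 fold change 2.69, camera adjusted p = 2.97e-136), with TP53I3 at 4.57 ± 0.10 in the authors' deposited table. Contractile genes were higher in 20 of 25 cases and lower in 1 (camera adjusted p = 1.01e-23), with CTGF at 4.47 ± 0.14, CYR61 at 3.58 ± 0.10 and ACTA2 at 3.28 ± 0.11 in the authors' deposited table. Interferon-stimulated genes were lower in 33 of 37 cases and higher in 2 (camera adjusted p = 1.3e-68), with MX1 at -3.46 ± 0.09 and IFIT3 at -2.41 ± 0.08 but TRIM22 at 2.82 ± 0.09 in the authors' deposited table. Lysosome genes were lower in 31 of 48 cases and higher in 6, cholesterol genes lower in 15 of 25 and higher in 2, and ATF4 genes lower in 20 of 30 and higher in 6 (camera adjusted p = 3.83e-07, 2.81e-06 and 1.26e-09). CTSH at -3.26 ± 0.14 and PHGDH at -1.95 ± 0.10 were among them in the authors' deposited table. NRF2 and BACH1 targets were lower in 23 of 30 cases and higher in 1 (camera adjusted p = 7.5e-08), with AKR1C1 at -2.12 ± 0.11 in the authors' deposited table. NF-kB targets were lower in 16 of 29 cases and higher in 8 (camera adjusted p = 0.000306, and adjusted p = 0.0597 with a preset correlation of 0.1), with CXCL1 at -3.56 ± 0.16 in the authors' deposited table. Fibroblast markers were lower in 7 of 16 cases and higher in 4 (camera adjusted p = 0.0302, and adjusted p = 0.19 with a preset correlation of 0.1).

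Mitosis genes were lower in 40 of 44 cases and higher in 1, and histone genes lower in 51 of 55, in the libraries labelled shFbxo22 senescent (camera adjusted p = 5.16e-17 and 1.52e-28). DNA replication genes were lower in 35 of 45 cases and higher in 5 (camera adjusted p = 3.84e-05, and adjusted p = 0.0597 with a preset correlation of 0.1). The replication clamp PCNA at 2.17 ± 0.10, TYMS at 2.09 ± 0.12 and the ligase LIG1 at 1.79 ± 0.12 went up, while MCM7 was at -1.69 ± 0.11, in the authors' deposited table. Homologous recombination genes were lower in 16 of 24 cases and higher in 2 (camera adjusted p = 0.00179, and adjusted p = 0.0886 with a preset correlation of 0.1). Secretory factors were split, with 21 higher and 21 lower of 46 (camera adjusted p = 0.919). INHBA was at 3.86 ± 0.14 and TNFAIP6 at -3.97 ± 0.14 in the authors' deposited table. Matrix genes, glutamine genes, glycolysis genes and FBXO22 partners gave camera adjusted p = 0.804, 0.582, 0.795 and 0.147. Glycolysis genes had a median of 0.03 and a mean of -0.05, and glutamine genes a median of -0.13 and a mean of 0.01, so these summaries differ in sign. Among genes above the median base mean, INPP5D at 7.86 ± 0.45, PDE4C at 7.45 ± 0.38, CLCA2 at 7.26 ± 0.22 and ANKRD1 at 6.84 ± 0.33 were the largest increases in the authors' deposited table. ADH1B at -7.10 ± 0.35, HSPA12B at -6.99 ± 0.47, NPTX2 at -6.51 ± 0.37, RASL12 at -6.42 ± 0.43 and CHI3L1 at -6.21 ± 0.16 were the largest decreases among them in the authors' deposited table.

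**Figure D2:**
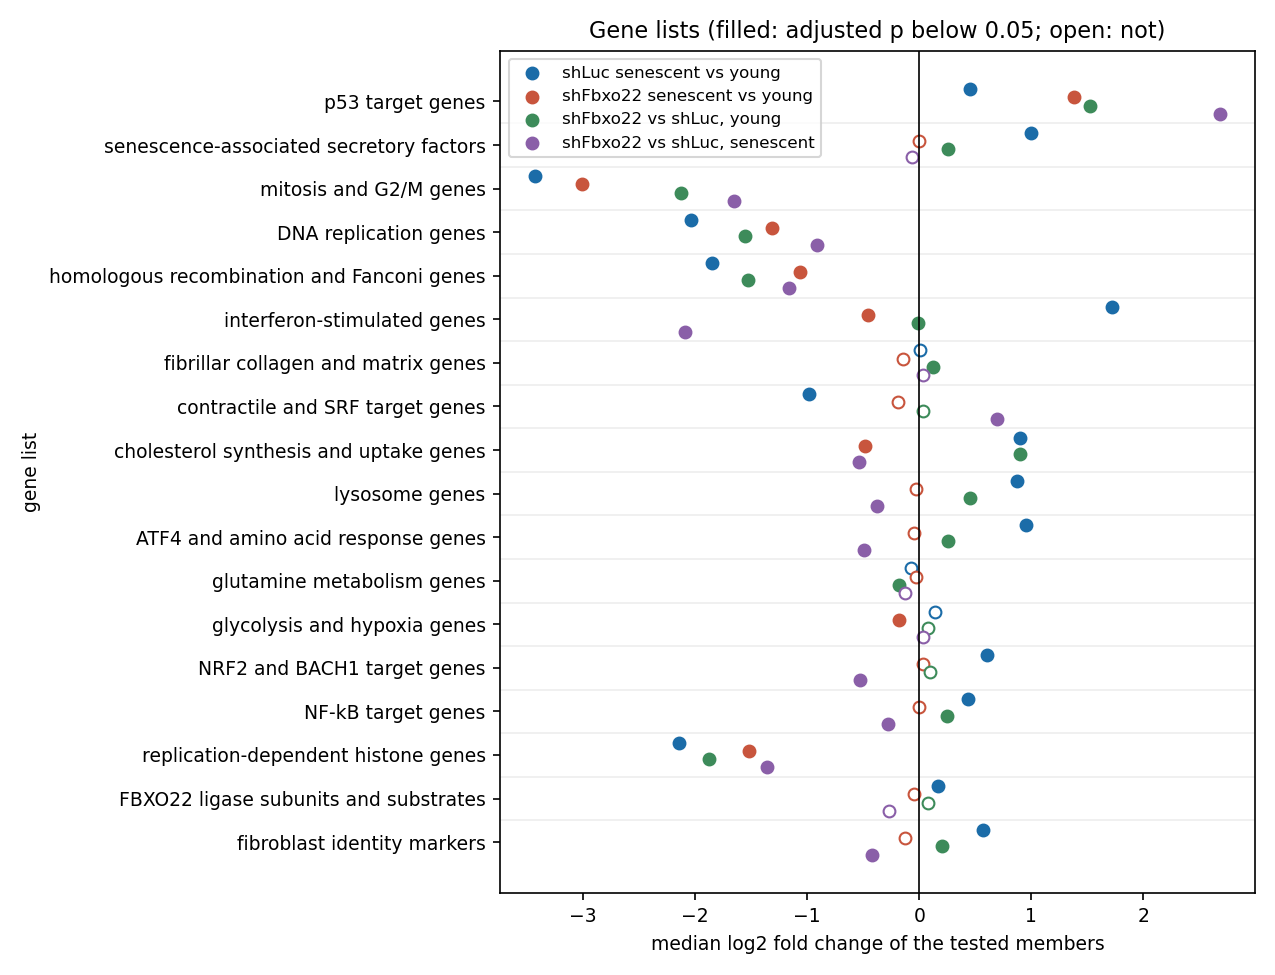
Median log2 fold change (horizontal axis) of the tested members of 18 gene lists with at least 10 members tested (vertical axis) in the 4 comparisons; filled points passed the camera test at adjusted p 0.05 and open points did not. The p53 target list lies at 0.45, 1.38, 1.52 and 2.69, and the interferon list at 1.72 for senescence in shLuc and at -2.09 between hairpins in senescent cells.

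Few markers of other cell types were tested. Of 17 keratinocyte markers between 7 and 10 were tested per comparison, of 8 melanocyte markers 2, of 9 endothelial markers 2 or 4, and of 12 blood cell markers 4 or 6. The smallest camera adjusted p of these lists was 0.0733, for endothelial markers in senescence of the libraries labelled shFbxo22, where TEK at -0.98 ± 0.21 and VWF at -0.96 ± 0.27 were lower in the authors' deposited table. With fold change as the statistic that list passed with adjusted p = 0.01, and the keratinocyte list with adjusted p = 0.0348 in shLuc senescence and 0.0362 between hairpins in young cells. The keratinocyte list otherwise gave camera adjusted p between 0.234 and 0.919, the melanocyte list between 0.147 and 0.955 and the blood cell list between 0.567 and 0.919. In shLuc senescence CD74 was at 2.43 ± 0.36 and HLA-DRA at 2.26 ± 0.55, both higher, in the authors' deposited table. Between hairpins in senescent cells the endothelial marker KDR was lower in the libraries labelled shFbxo22 with -4.65 ± 0.40 in the authors' deposited table (adjusted p = 9.02e-30). Of the 4 endothelial markers tested there, 2 were lower and 1 was higher. The epithelial cadherin CDH1 was lower with shFbxo22 in young cells, with -2.20 ± 0.51 in the authors' deposited table (adjusted p = 0.000108). In that comparison 3 keratinocyte markers were higher and 3 lower of 9 tested.

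The senescence response itself was then compared between the hairpins. It differed for 6873 of 18598 genes by the z test on the authors' deposited values (adjusted p below 0.05), 3505 with a more positive and 3368 with a more negative response in the libraries labelled shFbxo22. Of these, 987 were called in opposite directions in the authors' deposited tables, 606 that rose in shLuc and fell with shFbxo22 and 381 that fell in shLuc and rose with shFbxo22. The 2 tables' fold changes were moderated by different amounts, so some differences of genes with few reads may come from moderation. Among genes with a base mean of at least 50 in both, 6201 were called. The response of CDKN1A differed by a log2 value of 0.22 ± 0.14 (adjusted p = 0.22), that of LMNB1 by 0.28 ± 0.21 (adjusted p = 0.335) and that of MKI67 by -0.23 ± 0.16 (adjusted p = 0.283), none past the threshold, from the authors' deposited values. MDM2 differed by 3.06 ± 0.16, CDKN2B by -1.59 ± 0.21, CDKN2A by -1.11 ± 0.20, IL6 by -2.39 ± 0.18 and IL8 by -2.36 ± 0.37, all past it, from the authors' deposited values. KDM4A at -0.40 ± 0.20 did not pass (adjusted p = 0.102) from the authors' deposited values.

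Interferon-stimulated genes had a more negative response with shFbxo22 in 36 of 37 cases, cholesterol genes in 23 of 25 and lysosome genes in 36 of 48, with no member the other way (camera adjusted p = 1.35e-58, 4.16e-25 and 1.05e-18). ATF4 genes were more negative in 24 of 30 cases and more positive in 4, NF-kB targets in 16 and 3 of 28, NRF2 and BACH1 targets in 20 and 2 of 30, and fibroblast markers in 8 and 3 of 15 (camera adjusted p = 7.64e-13, 2.85e-07, 7.32e-07 and 3.7e-05). The fibroblast call ended on ranks, with adjusted p = 0.13. Secretory factors were more negative in 26 of 42 cases and more positive in 10 (camera adjusted p = 0.000243, and adjusted p = 0.0813 with a preset correlation of 0.1). FBXO22 partners were more negative in 3 of 10 cases and more positive in 1 (camera adjusted p = 0.0354, and adjusted p = 0.139). The p53 targets were more positive in 21 of 32 cases and more negative in 3, and contractile genes in 21 and 1 of 25 (camera adjusted p = 7.64e-12 and 5.7e-18). Mitosis genes were more positive, that is fell less, in 28 of 44 cases, and DNA replication genes were more positive in 23 of 45 and more negative in 1 (camera adjusted p = 1.07e-07 and 7.59e-08). Homologous recombination genes (14 of 24) and histone genes (24 of 54, with 5 more negative) gave camera adjusted p = 0.00889 and 0.0108, and adjusted p = 0.139 and 0.251 with a preset correlation of 0.1. The smaller fall of mitosis genes began from a lower level, since all 44 were already lower with shFbxo22 in young cells. In senescent cells 40 of the 44 were still lower than with shLuc. Matrix, glutamine and glycolysis genes gave camera adjusted p = 0.0547, 0.281 and 0.142, and the marker lists of other cell types between 0.153 and 0.785. With fold change as the statistic the keratinocyte list, 3 more positive of 6, passed with adjusted p = 0.00417. Among genes whose base mean, averaged over both senescence tables, lay above the median, the largest positive differences were ANKRD1 at 6.71 ± 0.39, ID1 at 5.66 ± 0.18, ID3 at 5.39 ± 0.17 and SERPINB7 at 4.39 ± 0.23, from the authors' deposited values. AGT at -6.10 ± 0.34, GLDN at -6.03 ± 0.33, COL15A1 at -5.82 ± 0.26, FABP3 at -5.48 ± 0.17 and CHI3L1 at -5.31 ± 0.26 were the largest negative ones among them from the authors' deposited values.

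**Figure D3:**
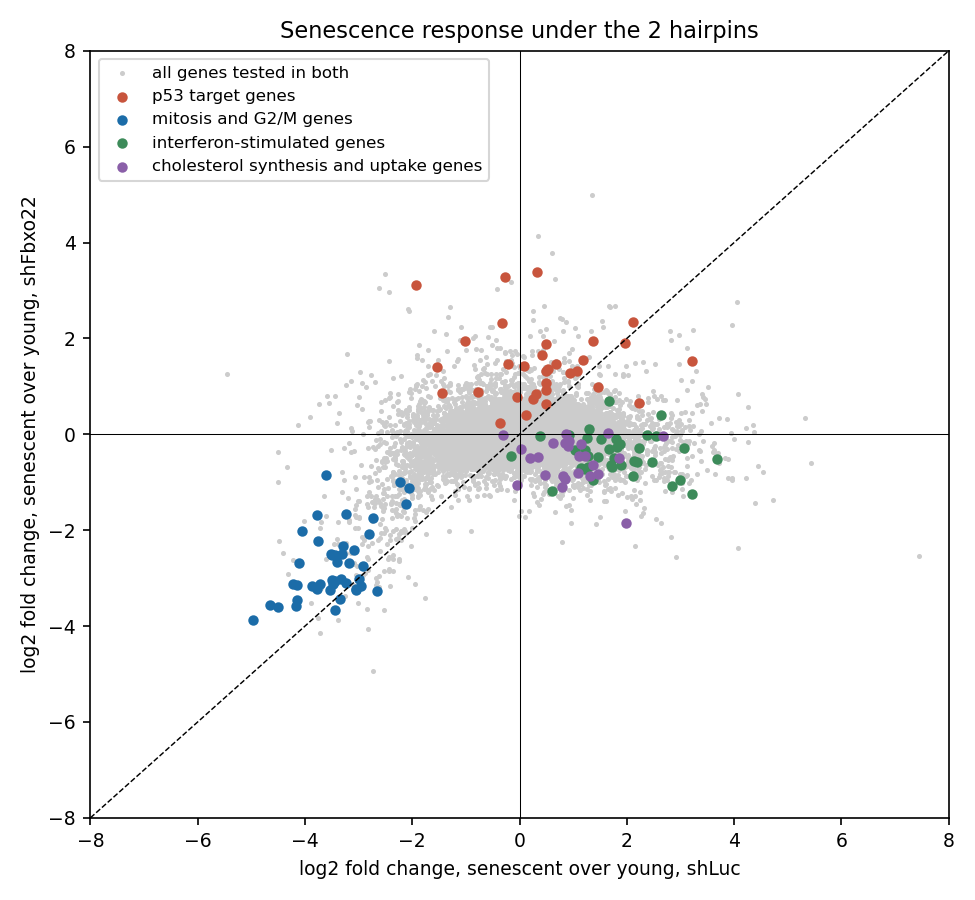
Log2 fold change of senescent over young cells with shLuc (horizontal axis) and in libraries labelled shFbxo22 (vertical axis) for each gene tested in both of the authors' deposited tables; the dashed line marks equal responses. Across genes Pearson's r was 0.23; mitosis genes lie low on both axes, and most interferon and cholesterol genes lie to the right of 0 and at or below 0 on the vertical axis.

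Calls were first set against each other for tables that share no library. Among 18598 genes tested for senescence under both hairpins, 491 rose in both and 851 fell in both, against 358 and 437 for independent lists, and 606 rose in shLuc and fell with shFbxo22 against 433, while 381 fell in shLuc and rose with shFbxo22 against 361. Across these genes Pearson's r was 0.23, and genes are not independent replicates. Between the hairpin comparisons in young and in senescent cells, 1591 genes were higher and 1403 lower in both among 19966, against 841 and 752 for independent lists, with r = 0.39 across genes. In opposite directions, 856 were higher with shFbxo22 in young and lower in senescent cells, against 821, and 539 the other way, against 770. Senescence in shLuc and the hairpins in young cells share the young shLuc libraries. There 2097 genes were higher and 2291 lower in both among 19959, against 840 and 809 for independent lists. Simulated unchanged groups gave a mean of 0 overlapping calls, which is no measure of the overlap that shared libraries add. Their correlation across genes was 0.55 against 0.50 simulated, and their covariance 0.344 against 0.0483 simulated. The 3 control libraries could not be split, so part of the excess may come from the shared controls.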

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

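All tests of explanations in this part were chosen after the results were seen. The results below were singled out because the senescence response differed between the 2 hairpins by a test of the difference itself, from the authors' deposited values. This held for 6873 genes in all, though unequal moderation of the 2 tables may account for some of those with few reads. Among single genes, the log2 difference of responses (libraries labelled shFbxo22 minus shLuc) was 1.77 for FBXO22, 3.06 for MDM2 and 5.66 for ID1, and it was -1.11 for CDKN2A, -2.36 for IL8 and -2.39 for IL6. Among lists, the median difference was -2.07 for interferon-stimulated genes, -1.56 for cholesterol genes, -0.74 for lysosome genes and 0.81 for contractile genes. The reconstructed means of ID1 from the authors' deposited tables were 2132 and 349.9 normalized counts in young and senescent shLuc libraries, and 283.9 and 2418 in young and senescent libraries labelled shFbxo22.

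FBXO22 was higher, not lower, in the senescent libraries labelled shFbxo22. This direction and the shares below rest on turning the sign of the senescent hairpin table. The best choice of signs that left that table unturned gave a mean absolute log2 difference of 0.2537 between estimates of group means, against 0.0092. An exchange of hairpin labels between the senescent groups would turn the hairpin effect around. Of the 75 genes at least 8-fold apart between hairpins in young cells, 92.0% kept their direction in senescent cells. Among all 4389 genes called in both hairpin comparisons the share was only 68.2%. For the 75 genes the share argues against an exchange, provided that the hairpin acted alike in both states, which was not tested. The wider share fell short of what this check had asked for and decides nothing. A second candidate explanation is that FBXO22 rose together with p53 targets: its senescence log2 change of 1.53 lay within the range of that list (0.24 to 3.38), above 20 of the 32 members, a range so wide that it tests little. In shLuc senescence FBXO22, at -0.25 and not called, also lay within the list's range (-1.92 to 3.21, median 0.45), which decides nothing, and between hairpins in young cells it was at -0.81 while all 32 members were higher, though there the label names FBXO22 as the hairpin's target. The hairpin and the rise of p53 targets cannot be told apart as sources of the FBXO22 level, because every library with the strongest rise carries the same hairpin, and loss of the hairpin's effect in those cells also stays open and untested.

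Fewer genes changed with senescence in the libraries labelled shFbxo22 (3325) than in shLuc (9321). Stronger moderation of that table's fold changes was checked with group means taken from the hairpin tables. The check covered only the 9109 genes with a base mean of at least 200 in every table. Among them, 247 were at least 2-fold apart with shFbxo22 against 1301 with shLuc. The senescence tables themselves gave 226 and 1276. These values argue against moderation for these genes only. Genes with fewer reads, where moderation is strongest, were not covered, so moderation stays open for them. Larger spread between libraries was weighed by the hairpin-table numbers, counted without regard to p, whose ratio, shFbxo22 over shLuc, was 0.190. This ratio cannot exclude spread, because moderated fold changes shrink more where spread is larger. Median standard errors in the shFbxo22 and shLuc senescence tables were 0.111 and 0.102, over 6062 genes with a base mean of at least 500. A biological explanation is that young cells with shFbxo22 may already have been shifted in part towards the senescent shLuc state. The covariance of the 2 sets of changes exceeded the simulated one by 0.296, part of which may come from the shared controls. Median log2 fold changes (shLuc senescence, then hairpins in young cells) were alike in direction for DNA replication (-2.04, -1.56) and cholesterol genes (0.90, 0.90). Contractile genes (-0.98, 0.03) showed no such shift. Interferon-stimulated genes (1.72, -0.01) were mixed between hairpins in young cells, with 16 higher and 7 lower of 37 and a mean of 0.28. Their camera adjusted p there was 0.00185, and adjusted p = 0.138 with a preset correlation of 0.1. The labels give neither the time after irradiation nor a batch, so differences in either stay open, and each hairpin may also differ by the cell population that carries it.

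All size factors were close to 1. The mean library total implied by each of the 4 tables ranged over 0.0050% of its mean, which is what counts brought to one total before the authors' test would give. A mean over 6 libraries does not show the totals of single libraries. Whether one distribution was imposed on every library stays open: at equal rank the 4 groups' mean counts differed by at most 1.05-fold between ranks 100 and 10000. Among the 10 most abundant rows they differed by up to 1.34-fold, which argues against it without excluding it, because means over 3 libraries do not show the order of rows within a library. Either step could have changed the size of every fold change, and no biological explanation was tested.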

How the results depend on the processing

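Alternatives marked here as added were chosen after the data were seen. Asking for at least a 2-fold change lowered the number of called genes, by its construction, to 3620 for senescence in shLuc, 738 for senescence in libraries labelled shFbxo22, 2212 for the hairpins in young cells and 3556 in senescent cells. Without the authors' low-expression filter these counts were 8791, 2837, 6529 and 8561, and the difference of responses was called for 6486 genes, all within 1.5 times. The added settings (a base mean of at least 50, an adjusted p of 0.01, median or trimmed-mean centring) kept these 5 counts within 1.5 times. Taking the difference from the hairpin tables called 6625 genes, and 6482 genes were called both ways, all with the same sign. FBXO22 kept its direction under 3 added settings (both centrings, which also kept its call, and group means of the senescence tables, which have no test), from -0.81 to -0.76 in young and from 1.0004 to 1.02 in senescent cells. All 872 added recalculations of single named genes kept direction and call, but each only subtracted a median or trimmed mean. These centres lay between -0.0100 and 0.0093 log2, so the outcome was nearly fixed in advance. The same holds for the centred counts and the centred FBXO22 values above. Of 88 list tests 50 passed, against 47 with fold changes, 42 with ranks, and 44 and 37 with preset correlations of 0.05 and 0.1; of 352 such recalculations 316 kept their call, 33 lost it, 3 gained it and 0 reversed. No paired analysis was possible because the tables hold no values per library. For the same reason other normalizations and tests, pseudocounts, a filter per library, a fit of all 12 libraries, an estimated correlation, fry, leaving out libraries and other splits of the libraries were not run; 3 against 3 gives 10 splits, so their share could not fall below 0.1. Depth limits the genes with few reads, whose fold changes are moderated most.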

Other observations

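Composition differed between the groups, as computed from the reconstructed group means. Mitochondrial genes took 0.971% of the mean counts in young and 1.32% in senescent shLuc libraries, and 1.62% and 1.88% in young and senescent libraries labelled shFbxo22. Short structural RNAs took 11.7% and 12.8% in the shLuc groups and 8.81% and 9.61% in the groups labelled shFbxo22. RN7SL1, the RNA of the signal recognition particle, was the most abundant row in every group. The 10 most abundant rows took between 10.7% and 11.2% in all 4 groups. These values have no error, since values per library were not analysed here.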
